A study of Mus musculus with 2 samples.

How the data were processed

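Cells from inflamed mouse lungs were profiled by single-cell RNA sequencing with a BD Rhapsody cartridge and the TAS-Seq library method, per the labels' protocols. Wild-type (WT) cells carried hashtag A961 and cells lacking interleukin 4 (IL-4 KO) carried hashtag A962, 2 oligonucleotide-tagged labels that mark the sample of origin. Cells of both genotypes shared 1 cDNA library and 1 hashtag library, and each genotype was 1 tagged cell sample without a replicate. About 10000 cells per sample were loaded, after a 25% and 65% Percoll gradient.

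The deposited cDNA table holds whole-number counts per gene and cell that the authors had split by hashtag into WT, IL-4 KO and cells with both hashtags. The submitters' processing notes name cutadapt 3.4, Bowtie2 2.4.2 and R 4.2.2 and the mouse build GRCm38 without saying which step each one served. The counting step and its annotation are not given in the sources used here, nor is whether a count stands for a read or a molecule. A second deposited table holds counts for the same library before the authors' background step. Compared value by value, that step set 254468 values of 91 genes to 0, up to a limit of its own for each gene, and left every other value as it was. The deposited hashtag table holds counts of each hashtag per barcode. The step before deposition that made its barcode list is not described beyond the file header.

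The corrected table had 13643 cells and 26518 genes, and the uncorrected one 13767 cells and 33327 genes. The 1110 cells with both hashtags were left out. Cells were kept with at least 200 genes detected and at most 25% mitochondrial counts. Scrublet, run in scanpy 1.11.5 with an expected doublet share of 8%, set a threshold that marked 0 cells. Its scores ranked the cells with both hashtags above other cells with an area under the curve of 0.739. No cell was removed by score in the main values, so doublets within a genotype remain in them.

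Counts were scaled to 10000 per cell and log-transformed. Cells of both genotypes were clustered together without the genotype, on 2000 variable genes without Il4 and Il13, 30 principal components, 15 neighbours and Leiden resolution 1 (seed 0, igraph 0.11.9). This gave 24 clusters. A cluster was named after the best scoring of 29 marker classes when at least 3 markers of the class were 1.5-fold above all other cells and detected in at least 10% of the cluster. The next class had to score under 0.8 of the best, and the 10 leading genes could hold no more markers of another class than its own. A cluster with no own marker among those 10 genes needed 0.667 of its class markers to be met. These naming thresholds were set after the data were seen. The markers are RNA markers, so each named class is a marker-defined class and not a sorted one. Genes Il9, Il3, Prss34, Tpsb2, Tpsab1, Mcpt4, Epx, Tcrg-C1 and Tcrg-V6 of the fixed lists and marker sets were not in the table.

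Classes with at least 100 kept cells in each genotype were compared. Counts were summed per gene, class and genotype and scaled by the class total to CPM. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, CPM carry exact Poisson 95% intervals, and the ratio of 2 CPM values carries the exact conditional binomial 95% interval of its counts. All of these intervals cover counting error only, and they leave out differences between animals, cells and preparations. If the counts are reads, several may come from 1 molecule, and the intervals are then too narrow even for counting error. No p-value was computed, since cells and genes of 1 tagged sample per genotype are not replicates. A ratio against 0 counts is given as a bound against 3 counts. Where no cell had a count, the share allowed is 3 cells of the class total, which is lower than the upper end of the Clopper-Pearson interval.

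Before the data were examined, the comparisons, the 20 gene lists, the marker sets, the first set of alternatives and the rule for named genes were fixed. The rule took the 10 highest and 10 lowest IL-4 KO to WT ratios in neutrophils, 5 and 5 in each macrophage or monocyte class and 3 and 3 in other classes. Genes were ranked by the interval bound nearest to 1, among genes with a mean of at least 50 CPM and at least 30 counts in the higher genotype. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes and unnamed gene models were left out of the ranking. Genes that the rule picked in a class they are markers of, Marco and Fabp1 in alveolar macrophages and Apoe in monocyte-derived or interstitial macrophages, are not given as results there. Single members of the lists that are named as examples were chosen after their values were seen.

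The lists covered neutrophil cytokines and chemokines, granule genes, activation and ageing markers, anti-apoptotic and pro-apoptotic genes, NADPH oxidase and antioxidant genes, the IL-4 and STAT6 response, type 2 cytokines, efferocytosis, tissue repair, interferon response, NF-kB and inflammasome genes, MHC class II presentation, cell cycle, hypoxia and glycolysis, lipid metabolism, dissociation stress, mitochondrially encoded genes, T cell activation, and RNA of erythroid, epithelial and plasma cells. A list was summarised by the median log2 ratio over members with a mean of at least 10 CPM, where at least 5 members reached it. Its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression, describes these cells and is not a test. Receptor transcripts were also counted after each cell was thinned to 2000 counts.

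Alternatives were Leiden resolutions 0.5 and 2, a stricter filter of 500 genes and 10% mitochondrial counts, the uncorrected table, thinning, edgeR 4.0.16 TMM factors under R 4.3.3, median-of-ratios factors, means over cells, other filters and summaries for the lists, and reassignment of cells from the hashtag counts at 2, 3 and 10 times. Further alternatives were chosen after seeing the data. They leave out 1145 cells with the highest Scrublet scores, the cell with the most counts of a gene, neutrophil cluster 16, or list members within 20 Mb of Il4, or they count cluster 4 as neutrophils or cluster 1 as monocyte-derived or interstitial macrophages. The number 1145 is that of doublets within a genotype expected from the 1110 cells with both hashtags. Coordinates are GENCODE gene models on GRCm38. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

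The gene and list steps were tested on simulated class sums with 26518 genes and 200 genes altered by known folds. Median recovered folds were 0.250, 0.503, 2.00 and 4.00 for true folds of 0.25, 0.5, 2 and 4, 50 genes each. The 95% interval held the true fold for 100%, 98%, 96% and 90% of those genes and for 95.3% of 6572 unaltered genes. All 20 genes that the naming rule picked were altered ones. Of 200 lists of 15 unaltered genes, 3.5% fell outside the central 95% of random lists. A list of 15 genes altered 2-fold had a median of 1.82-fold. Unlike the single-gene folds, this value was not corrected for the altered total of the simulated counts. The simulated sums were independent Poisson counts per gene, the model that the intervals assume. They therefore check the calculation only, and not counts that gather in few cells or genes that vary together.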

Results

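Single cells of mouse lung were sequenced 6 days after LPS (20 mg/kg, from Escherichia coli O111:B4) was given into the trachea, a model of acute respiratory distress syndrome studied here as inflammation resolves. The male C57BL/6 mice were 7 to 11 weeks old and were either wild-type (WT) or lacked interleukin 4 (IL-4 KO), a type 2 cytokine that acts on macrophages, lymphocytes and other cells. The question put to the data is how lung cells of the genotypes differ at that time. After filtering, 5457 WT cells with 146015900 summed counts and 7006 IL-4 KO cells with 189041338 summed counts were compared. WT cells had a median of 13307 counts (3629 to 297199) and 1938 genes, and IL-4 KO cells had 11682 counts (3600 to 247246) and 1811 genes. Cells of both genotypes were tagged and pooled in 1 library, with 1 tagged sample per genotype, so no difference below has a replicate check, and the 95% intervals cover counting error only, and not all of it if counts are reads. Of 12533 cells given a single genotype by the authors, 12530 (99.98%) had the larger hashtag count of that genotype. The authors split the cells by hashtag, so this agreement is no separate check of the genotypes. When the larger hashtag had to be at least 3 times the other, 91.7% of WT cells (90.9 to 92.4%) and 95.9% of IL-4 KO cells (95.4 to 96.3%) kept their genotype, 0 cells took the other one and the rest were left out. At 10 times the shares were 66.9% and 73.4%.

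Il4 (chromosome 11, 53602982 to 53618669 on GRCm38), the targeted gene, was not absent from cells labelled IL-4 KO. It had 48 counts in 18 of 5457 WT cells (0.329 CPM, 0.242 to 0.436) and 219 counts in 97 of 7006 IL-4 KO cells (1.16 CPM, 1.01 to 1.32). The cells differed between genotypes. In cluster 18, which holds dendritic cell and basophil transcripts, 19 counts came from 5 of 123 WT cells (5.95 CPM, 3.58 to 9.29), and 0 of 144 IL-4 KO cells had a count, which allows a share of up to 2.08% (3 cells of the class). Of cells with at least 3 of 7 basophil markers, this cluster held 13 in WT and 4 in IL-4 KO. T cells, a known source of the cytokine, held 17 counts in WT (2.78 CPM, 1.62 to 4.45) and 11 in IL-4 KO (2.64 CPM, 1.32 to 4.73), in 4 cells each. Outside T cells and cluster 18, WT cells had 12 counts (0.0878 CPM, 0.0454 to 0.153) and IL-4 KO cells 208 (1.15 CPM, 0.996 to 1.31). IL-4 KO endothelial cells reached 5.29 CPM (3.54 to 7.60; 4% of cells with a count) against 0.210 CPM (0.00533 to 1.17; 0.275%) in WT. IL-4 KO neutrophils had 2.4 CPM (1.76 to 3.20) in 0.897% of cells, and 0 of 655 WT neutrophils had a count, which allows a share of up to 0.458%. NK cells, which had a median of 9188.5 counts in WT and 11910 in IL-4 KO, had no Il4 count in either genotype, which allows shares of up to 1.28% and 2.16%. Thinning every cell to 2000 counts gave 1.28 CPM in WT and 2.07 CPM in IL-4 KO over all cells. The labels do not say which part of Il4 is missing, so transcripts outside that part can still be counted, and the counts do not check the genotype.

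**Figure D1:**
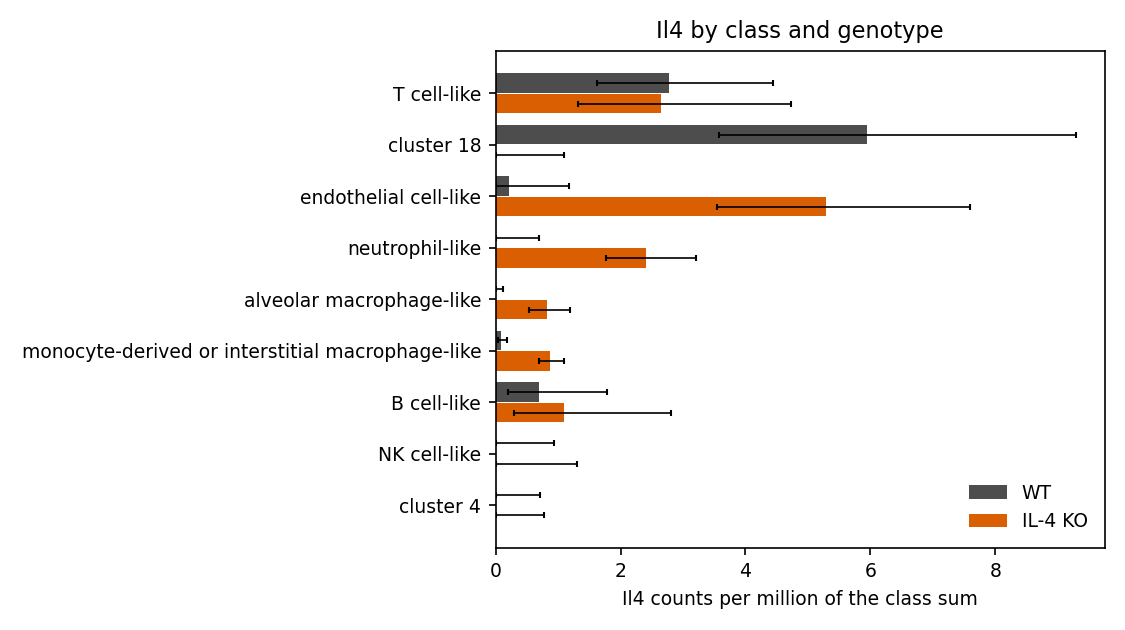
Il4 in CPM of the class sum (horizontal axis) for each class with at least 100 cells per genotype, WT in grey and IL-4 KO in orange, with exact Poisson 95% intervals as bars. Cluster 18 carries 5.95 CPM in WT and 0 in IL-4 KO, while endothelial cells carry 0.210 CPM in WT and 5.29 CPM in IL-4 KO.

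Il13 (chromosome 11, 53631324 to 53634702), the neighbouring type 2 cytokine gene, had 57 counts in 5 WT cells (0.390 CPM, 0.296 to 0.506) and 1 count in IL-4 KO (0.00529 CPM, 0.000134 to 0.0295). Of the WT counts, 40 came from 1 cell in the monocyte-derived or interstitial macrophage class. The list of type 2 cytokines and alarmin receptors had fewer than 5 measured members in every class and has no median.

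Neutrophils took a larger share of IL-4 KO cells. They were 2342 of 7006 IL-4 KO cells (33.4%, 32.3 to 34.5%) and 655 of 5457 WT cells (12%, 11.2 to 12.9%), a 2.79-fold difference in share. With the unnamed cluster 4 counted among them the shares were 41.3% and 22.2%, a smaller fold difference. Lymphocytes had the opposite direction: T, B and NK cells together were 20.5% of WT cells (19.5 to 21.6%) and 9.06% of IL-4 KO cells (8.40 to 9.76%). T cells were 7.93% (7.23 to 8.68%) and 3.80% (3.36 to 4.27%), B cells 8.32% (7.60 to 9.08%) and 3.28% (2.88 to 3.73%), and NK cells 4.29% (3.77 to 4.86%) and 1.98% (1.67 to 2.34%). Monocyte-derived or interstitial macrophages, named together because their markers overlap, were 30.3% of WT cells (29.1 to 31.5%) and 25.5% of IL-4 KO cells (24.4 to 26.5%), but 31.7% and 31.6% with the unnamed cluster 1 counted among them. Alveolar macrophages, the resident phagocytes of the airspace, were 9.46% (8.69 to 10.3%) and 7.04% (6.45 to 7.66%). Endothelial cells were 6.67% (6.02 to 7.36%) and 5.35% (4.84 to 5.91%). Classical monocytes were 2.03% and 1.16%, nonclassical monocytes 1.81% and 0.614%, fibroblasts 0.880% and 0.300%, erythroid cells 0.641% and 0.314%, and ciliated cells 0.202% and 0.0856%, each with fewer than 100 cells in a genotype. Shares sum to a whole, so a higher share of one class lowers the others. At Leiden resolution 2 the monocyte-derived or interstitial macrophage class had 15.5% of WT and 9.93% of IL-4 KO cells.

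Clusters without a name held 15.5% of WT cells (14.5 to 16.5%) and 17.2% of IL-4 KO cells (16.3 to 18.1%). Cluster 4, led by Itpr2, Mdm2, Ddit3 and Ccl3, was 10.2% of WT (9.43 to 11.1%) and 7.84% of IL-4 KO (7.22 to 8.49%). None of 10 neutrophil markers was raised enough in it to name it, though that class scored best. The rule compares with all other cells, which include the named neutrophils. Cluster 4 had S100a8 at 12379 CPM (67.7% of cells) and Csf3r at 469 CPM (58.8%), against 3845 and 118 CPM in cluster 1. Counting it as neutrophils put that class at 22.2% of WT and 41.3% of IL-4 KO cells. Cluster 1, led by Cxcl9, Ly6c2 and Nos2, was 1.45% of WT (1.15 to 1.80%) and 6.09% of IL-4 KO (5.55 to 6.68%), and 427 of its 506 cells were IL-4 KO. Cluster 18 was 2.25% and 2.06%, cluster 21, led by Lars2, Malat1 and Neat1, 0.367% and 0.885%, and cluster 22, with alveolar type 2 and endothelial genes, 1.19% and 0.314%.

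**Figure D2:**
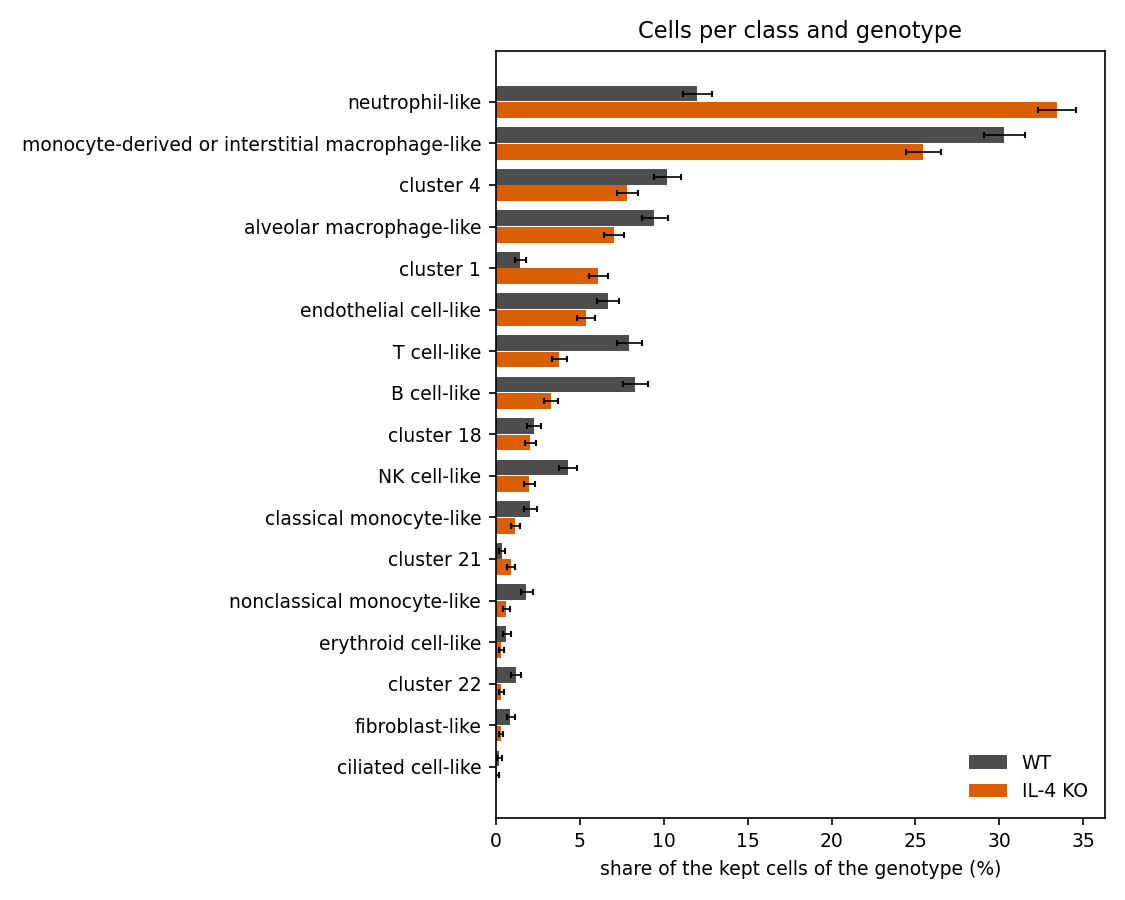
Share of the kept cells of each genotype (horizontal axis, percent) for each class or unnamed cluster, WT in grey and IL-4 KO in orange, with exact binomial 95% intervals as bars. Neutrophils are 12% of WT and 33.4% of IL-4 KO cells, and B, T and NK cells are each lower in IL-4 KO.

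IL-4 KO neutrophils had more transcripts of chemokines and interferon-inducible genes. Cxcl3 (chromosome 5, 90786103 to 90789600), a neutrophil-attracting chemokine, was 6.63-fold higher (5.55 to 7.97; 24.3 CPM in WT and 160.8 in IL-4 KO), though 3.22-fold in the uncorrected table and 4.31-fold at Leiden resolution 2. Its counts came from only 8 of 655 WT and 115 of 2342 IL-4 KO neutrophils. Cxcl9 (chromosome 5, 92321347 to 92328079), a chemokine for activated T cells, was 6.69-fold higher (5.55 to 8.13), with counts in 23 WT and 124 IL-4 KO cells. Gbp2 (chromosome 3, 142620602 to 142638008), a guanylate-binding protein, was 3.08-fold higher (2.88 to 3.29), and Cxcl10 2.89-fold (2.75 to 3.05). The immunity-related GTPase genes Tgtp2 (3.90-fold, 3.46 to 4.41), Igtp (3.27-fold, 3.01 to 3.57), Ifi47 (3.23-fold, 2.93 to 3.56) and Tgtp1 (3.21-fold, 2.88 to 3.59) were higher too, and all of them lie on chromosome 11 within 20 Mb of Il4. Chil3 (chromosome 3, 106147554 to 106167564), a chitinase-like protein of neutrophils and macrophages, was 3.24-fold higher (3.13 to 3.35; 682 and 2211 CPM). Of the 24 measured interferon response genes, 22 were higher in IL-4 KO, with a median log2 ratio of 0.41 that lay above every random list. Gbp5 (2.93-fold, 2.64 to 3.27) and Irgm1 (2.81-fold, 2.57 to 3.09) were among the higher ones. Isg15 (1.22-fold, 1.18 to 1.27) and Rsad2 (1.02-fold, 0.969 to 1.08) were close to equal, and Ifit3 was 1.43-fold lower (1.31 to 1.58). Cluster 16, led by Cxcl10, Rsad2 and Isg15, held 26.0% of IL-4 KO neutrophils (24.2 to 27.8%) and 12.7% of WT ones (10.2 to 15.5%). Without it, Cxcl9 was 2.58-fold and Cxcl10 1.49-fold higher, the Rsad2 ratio was 0.593 and the Ifit3 ratio 1.28.

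Inflammatory and granule genes were also higher as groups over the IL-4 KO neutrophil class, whose clusters differed in share. Cluster 5, led by S100a8 and Il1r2, held 58.8% of WT neutrophils (54.9 to 62.6%) and 42.9% of IL-4 KO ones (40.9 to 44.9%), and cluster 15, with stefin genes, held 5.19% (3.62 to 7.18%) and 12.7% (11.4 to 14.1%), so these values do not separate the mix of clusters from levels within cells. Of 14 cytokine and chemokine genes, 10 were higher (median log2 ratio 0.37), with Cxcl2 at 1.57-fold (1.56 to 1.59), Il1a, an alarm cytokine, at 1.5-fold (1.44 to 1.55) and Ccl4 at 1.43-fold (1.39 to 1.46), while Tnfsf14 was 1.94-fold lower (1.59 to 2.36). Of 13 granule and maturation genes, 9 were higher (0.41), with the siderophore-binding Lcn2 at 2.20-fold (2.16 to 2.24), Wfdc21 at 2.18-fold (2.13 to 2.23) and Cd177 at 1.69-fold (1.52 to 1.89). The others included Camp, with a ratio of 0.754 (0.413 after thinning), and Ngp, also lower, with a ratio of 1.03 without cluster 16. Of 19 NF-kB and inflammasome genes, 16 were higher (0.29), with Irak3, a brake on Toll-like receptor signalling, at 2.0-fold (1.85 to 2.17), Pycard at 1.68-fold (1.58 to 1.78) and Tnfaip3 at 1.53-fold (1.42 to 1.65). Of 9 anti-apoptotic genes, 8 were higher (0.17), with Bcl2l1 at 1.66-fold (1.51 to 1.84), and of 16 activation and ageing markers 10 were higher (0.14), with Icam1 at 1.60-fold (1.51 to 1.68) and Cxcr4, a receptor linked to neutrophil ageing, 1.38-fold lower (1.29 to 1.48). These medians lay at or above percentile 97.6 of random lists. The median over all measured genes in this class was −0.11, and TMM and median-of-ratios factors shifted all log2 ratios by 0.14.

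The IL-4 and STAT6 response list did not stand apart in neutrophils, with 5 of 11 genes higher and a median log2 ratio of −0.13 (percentile 42.6). Its members went both ways, with Socs1, a feedback inhibitor of cytokine signalling, 3.42-fold higher (2.54 to 4.68; 1.63-fold without cluster 16) and Egr2 2.18-fold lower (1.85 to 2.56). Medians near that of all genes were also found for pro-apoptotic genes (−0.11), NADPH oxidase and antioxidant genes (0.07), hypoxia and glycolysis (0.02), lipid metabolism (0.09), efferocytosis (0.00), tissue repair (−0.02), dissociation stress (−0.04), cell cycle (−0.21) and mitochondrially encoded genes (−0.25).

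Among genes with lower levels in IL-4 KO neutrophils, Pttg1 (chromosome 11, 43420250 to 43426251), a regulator of chromosome separation, was 5.20-fold lower (4.76 to 5.67; 235.8 and 45.4 CPM) and is near Il4. Nr4a2, an immediate early nuclear receptor, was 2.38-fold lower (2.14 to 2.65), and the histone genes H2bc4 and H4c9 were 2.29-fold (2.17 to 2.41) and 2.16-fold (2.0 to 2.33) lower. Other named genes rested on few cells. Retnla was 13.6-fold lower (12.2 to 15.3) with counts in 3 WT and 4 IL-4 KO cells, and Cbr2 4.50-fold lower (3.96 to 5.11; ratio 0.0918 with the stricter cell filter) with 2 and 3 cells. H2-Ab1 was 3.39-fold lower (2.98 to 3.85) and H2-Aa 3.24-fold lower (2.87 to 3.66), with counts in 10 and 11 WT cells, but their ratios were 1.77 and 1.73 once the cells with the highest Scrublet scores were left out. The MHC class II list had 8 of 9 genes lower (median log2 ratio −1.09) and turned to 0.19 under the same alternative, and Crip1, 2.24-fold lower (2.03 to 2.46), turned to a ratio of 1.30. RNA of erythroid, epithelial and plasma cells was lower as a group (−0.87, 4 of 5 genes), and 0.03 in the uncorrected table. The airway secretory genes Scgb3a1 and Scgb1a1 followed single cells: 96.6% of the Scgb3a1 counts of IL-4 KO came from 1 cell, and the 67.8-fold higher value (39.6 to 127.4) was 4.25-fold without it and 1.10-fold at Leiden resolution 2. Scgb1a1 was 2.27-fold lower (2.23 to 2.31) and had a ratio of 3.68 when genotypes were reassigned from hashtag counts at 3 times.

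**Figure D3:**
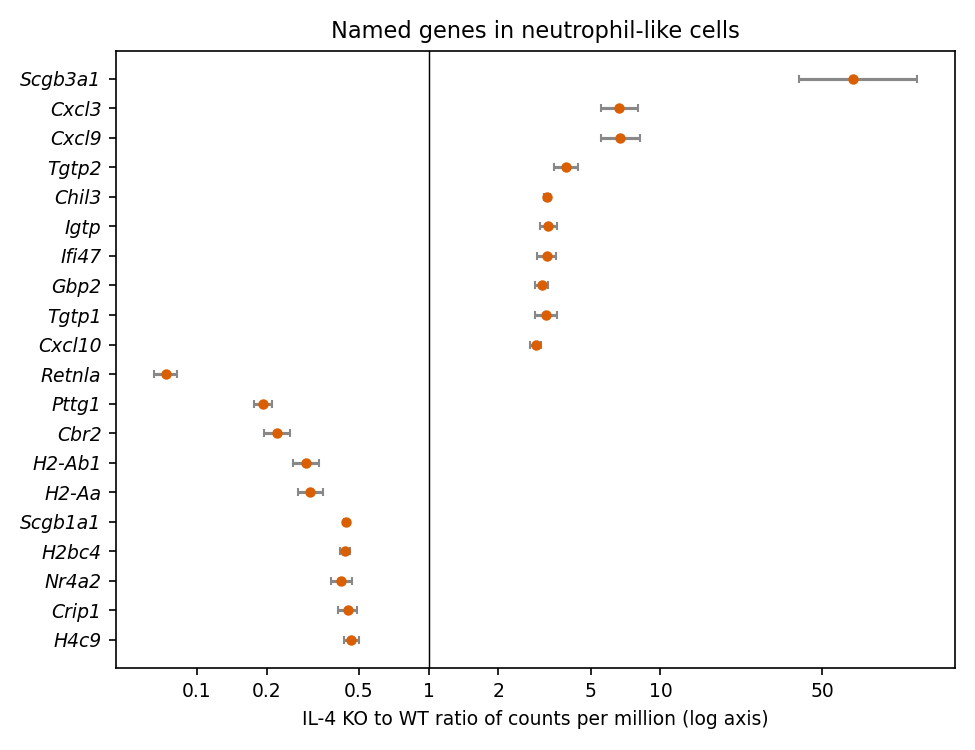
IL-4 KO to WT ratio of CPM (horizontal log axis) of the named genes in neutrophils, points with exact conditional 95% intervals as bars and a line at 1. Cxcl3 and Cxcl9 lie at 6.63 and 6.69, and Pttg1 lies at 0.192.

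IL-4 KO alveolar macrophages had higher interferon-inducible and cell cycle genes and lower IL-4 and STAT6 response genes. The serpin gene Serpina3g (chromosome 12, 104236245 to 104241939) was 7.44-fold higher (6.67 to 8.32; 11.9 and 88.4 CPM). Cxcl9 was 4.27-fold higher (4.05 to 4.49; 6.74-fold after thinning), Gbp2 3.51-fold (3.31 to 3.72) and Cxcl10 3.46-fold (3.29 to 3.65). Of 17 interferon response genes 13 were higher (median log2 ratio 0.96, above every random list), with Igtp at 2.82-fold (2.54 to 3.13). Of 16 IL-4 and STAT6 response genes 12 were lower (−0.39, below every random list). Pparg, a nuclear receptor of lipid metabolism, was 2.06-fold lower (1.95 to 2.18), Flt1 2.5-fold (2.28 to 2.74), Klf4 1.83-fold (1.72 to 1.95) and Mrc1, the mannose receptor, 1.37-fold (1.33 to 1.41). Arg1, an arginine-degrading enzyme on the same list, was 2.45-fold higher (2.34 to 2.58), and 4.67-fold without the highest Scrublet scores.

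Tissue repair genes were lower in 11 of 12 cases in IL-4 KO alveolar macrophages (−0.32, percentile 0.04), with the epidermal growth factor receptor ligand Areg 3.84-fold lower (3.51 to 4.22) and Igf1 1.74-fold lower (1.57 to 1.93). Lipid metabolism genes were lower in 13 of 18 cases (−0.25), with the cholesterol exporter Abcg1 2.19-fold lower (2.10 to 2.29). MHC class II genes were lower in 7 of 7 cases (−0.65), with Cd74 2.16-fold lower (2.13 to 2.19) beside a ratio of 0.156 (0.137 to 0.177) for the B cell and plasma cell gene Igkc, and cytokine genes in 10 of 13 (−0.26), with Cxcl1 2.01-fold (1.95 to 2.06) and Ccl6 1.99-fold lower (1.97 to 2.0). The stress gene Gadd45g was 2.88-fold lower (2.73 to 3.04), Ifi27l2a 3.25-fold (3.14 to 3.37), Cdc42ep3 2.84-fold (2.63 to 3.07) and H2-Q6 2.49-fold (2.31 to 2.67). Cell cycle genes were higher in 19 of 20 cases (0.50), with Ube2c at 1.71-fold (1.62 to 1.81) and Rrm2 at 1.69-fold (1.59 to 1.79). The cycling cluster 17 held 24.1% of IL-4 KO alveolar macrophages (20.4 to 28.2%) and 12.4% of WT ones (9.68 to 15.6%). Hypoxia and glycolysis genes were higher in 15 of 16 cases (0.24), with Ldha at 1.43-fold (1.40 to 1.46). Dissociation stress genes, which respond to tissue handling, moved beside these groups, with 13 of 16 lower (−0.50) and Fosb 2.14-fold lower (2.06 to 2.23).

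IL-4 KO macrophages of the monocyte-derived or interstitial class had more Mmp12, Pf4, Arg1 and Chil3. Mmp12 (chromosome 9, 7344381 to 7369499), the macrophage elastase, was 3.62-fold higher (3.53 to 3.71), Pf4 3.24-fold (3.20 to 3.28), Arg1 2.54-fold (2.51 to 2.57) and Chil3 2.42-fold (2.39 to 2.44). The clusters behind the class differed, and cluster 2, which is itself led by Pf4, Arg1, Mmp12 and Spp1, held 40.4% of the IL-4 KO class (38.1 to 42.7%) and 17.7% of the WT class (15.9 to 19.7%). Cluster 6, led by Apoe and Ly6c2, held 50.3% in WT (47.9 to 52.7%) and 41.7% in IL-4 KO (39.4 to 44.0%), cluster 3 held 18.2% and 11%, and cluster 7, with the complement C1q genes, 13.8% and 6.95%. Marco, an alveolar macrophage marker, was 6.33-fold higher (6.06 to 6.62), and 9.84-fold without the cell with the most counts of each genotype. The neutrophil-type genes Csta2 (5.02-fold, 4.73 to 5.33; 2.99-fold after thinning and 9.85-fold at Leiden resolution 2) and Wfdc21 (3.47-fold, 3.42 to 3.51) were higher, beside 5 of 6 granule genes (median log2 ratio 0.78). S100a8, the most abundant neutrophil marker here, was 1.81-fold higher (1.80 to 1.83) in the same class.

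Although Arg1, Chil3 and Mmp12 belong to the IL-4 and STAT6 response list, that list as a whole did not stand apart in these macrophages, with 8 of 13 genes lower (−0.01, percentile 32.2). Klf4 was 2.09-fold lower (2.02 to 2.17), Ccl8 1.94-fold (1.87 to 2.01) and Egr2 1.79-fold (1.71 to 1.88). Cytokine genes were lower in 11 of 13 cases (−0.32), with the prostaglandin synthase Ptgs2 2.08-fold lower (2.03 to 2.14) and Ccl3 1.61-fold lower (1.59 to 1.62), whereas Cxcl3 was 2.59-fold higher (2.54 to 2.64; 5.35-fold at Leiden resolution 2). Ccl7, a monocyte-attracting chemokine, was 3.07-fold lower (2.94 to 3.20; ratio 0.182 after thinning), Cd83 3.04-fold (2.90 to 3.18), Fbxo32, a ubiquitin ligase subunit, 3.03-fold (2.89 to 3.17) and Cited2 2.31-fold (2.23 to 2.4). Genes of the NADPH oxidase and antioxidant list were higher in 12 of 15 cases (0.22), with Prdx5 at 1.69-fold (1.68 to 1.71) and Hmox1 at 1.39-fold (1.36 to 1.41). Interferon response genes split, with 8 of 14 higher (0.50), Gbp2 2.90-fold higher (2.73 to 3.09) and Irf7 1.51-fold lower (1.43 to 1.59), and the median was −0.03 without the members within 20 Mb of Il4. With cluster 1, which is led by interferon-inducible genes and is mostly IL-4 KO, the medians were 1.14 and 1.11, the Gbp2 ratio 5.35 and the Irf7 ratio 0.964. Dissociation stress genes were lower in 17 of 17 cases (−0.52), with Jun 2.19-fold lower (2.15 to 2.22).

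NK cells, though fewer in IL-4 KO, had more effector transcripts, while single effector genes of T cells depended on how cells were summed. In NK cells, 8 of 9 T cell activation and effector genes were higher (median log2 ratio 1.01, above every random list). Ifng, the gene of interferon gamma, was 2.45-fold higher (2.21 to 2.72; 143.6 and 351.6 CPM), Gzmb, a cytotoxic granule protease, 2.01-fold (1.89 to 2.14) and Tnfrsf9 2.67-fold (2.19 to 3.28). Anti-apoptotic genes were higher in 9 of 11 cases (0.53), and 12 of 16 interferon genes were higher (0.55), a median that turned to −0.10 at Leiden resolution 2 and −0.15 without the highest Scrublet scores. In T cells, 9 of 13 activation genes were higher (0.31, percentile 99.4). Ifng was 2.02-fold higher (1.77 to 2.31), but 1.29-fold after thinning and 1.10-fold as a mean over cells. Gzmb in T cells was 2.09-fold higher (1.78 to 2.44), with ratios of 1.10 after thinning and 0.945 as a mean over cells, and Tnfrsf9 4.52-fold (3.28 to 6.33) with counts in 11 WT and 16 IL-4 KO cells. Interferon response genes were higher in 17 of 18 cases in T cells (0.85), with Gbp2 at 2.84-fold (2.32 to 3.49) and Igtp at 2.49-fold (2.17 to 2.86), and hypoxia and glycolysis genes in 15 of 16 (0.31), with Pkm at 1.61-fold (1.48 to 1.75).

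Transcripts of myeloid cells moved with the lymphocyte classes. In T cells, Chil3 was 5.34-fold higher (4.82 to 5.91), AA467197 3.80-fold (3.45 to 4.19) and Wfdc21 3.34-fold (2.98 to 3.74), and without the highest Scrublet scores Chil3 was 1.33-fold higher and the Wfdc21 ratio 0.623. Lower in T cells were the MHC class II genes H2-Eb1 (6.68-fold, 5.96 to 7.52) and H2-Ab1 (5.50-fold, 4.98 to 6.08), with ratios of 0.335 and 0.409 after thinning, beside Igkc (ratio 0.0866, 0.0815 to 0.0920; 72.1% of WT counts in 1 cell), and the plasma cell gene Jchain, at least 165-fold lower, came from 1 WT cell. S100a8 was 2.38-fold higher (2.31 to 2.45) in T cells and 2.15-fold higher (2.07 to 2.23) in NK cells. In NK cells, Wfdc21 was 7.89-fold higher (7.06 to 8.83; 3.92-fold and 4.10-fold at Leiden resolutions 0.5 and 2, and 5.16-fold in the uncorrected table), Cxcl3 9.54-fold (7.71 to 11.9; ratio 0.701 at Leiden resolution 0.5) and Retnlg 8.63-fold (6.81 to 11.1; 1.29-fold without the top cell), while Mmp12 (11.2-fold, 8.04 to 15.9; 75.5% of WT counts in 1 cell; ratio 0.00293 with the stricter cell filter), Apoe (5.37-fold, 5.18 to 5.57; ratio 0.739 at Leiden resolution 2) and C1qc (3.58-fold, 3.10 to 4.16) were lower. In B cells, Ear2 was at least 199.9-fold higher, from 4 IL-4 KO cells, Prg2 216-fold (73.5 to 1053; 33.1-fold without the top cell) and Ngp 37.7-fold (23.6 to 64.2; 4.59-fold without the top cell), both with over 90% of counts in 1 cell. Lower in B cells were the acute phase gene Saa3 (2.22-fold, 2.18 to 2.25; ratio 0.852 after thinning), Ccl2 (2.39-fold, 2.11 to 2.71; ratio 0.144 with the stricter cell filter) and Ms4a7 (2.91-fold, 2.51 to 3.39; ratio 1.02 with the stricter cell filter). B cells had 15 of 17 interferon genes higher (0.74), with Igtp at 3.66-fold (2.87 to 4.71), and 10 of 10 MHC class II genes lower (−0.51), with H2-Aa 1.41-fold lower (1.38 to 1.45). The IL-4 and STAT6 response list had 8 of 13 genes higher in NK cells (0.48, percentile 99.8), turning to −0.14 at Leiden resolution 0.5 and −0.24 without the highest Scrublet scores. In B cells 8 of 14 were lower (−0.22, percentile 0.51), turning to 0.31 over members of at least 50 CPM.

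IL-4 KO endothelial cells had higher interferon-inducible and lower cell cycle genes. Of 21 interferon response genes 17 were higher (median log2 ratio 0.56), with Gbp5 at 3.56-fold (3.05 to 4.16), Gbp2 at 3.38-fold (3.08 to 3.73) and Igtp at 3.14-fold (2.80 to 3.53). All 13 measured cell cycle genes were lower (−1.12, below every random list), with Cdk1, the mitotic kinase, 6.27-fold lower (4.23 to 9.59; ratio 0.0693 after thinning) in counts from 24 WT and 11 IL-4 KO cells. Pttg1 was 7.56-fold lower (5.89 to 9.83; ratio 0.0799 after thinning). All 18 dissociation stress genes were lower beside them (−1.20), with Egr1 4.90-fold lower (4.48 to 5.36; ratio 0.0976 without the highest Scrublet scores) and Fosb 3.01-fold lower (2.74 to 3.31), and RNA of other cells was higher in 3 of 6 cases (0.50) but −0.43 in the uncorrected table. Lcn2 was 4.27-fold higher (4.01 to 4.56), Cstdc4 5.37-fold (4.58 to 6.32) and Mt2 4.59-fold (3.88 to 5.45), the last 2 at 1.32-fold and 1.69-fold without the highest Scrublet scores. The adipocyte genes Car3 and Cfd came from 5 WT cells, with Car3 at least 855-fold lower and a Cfd ratio of 0.000368 (9.3e-06 to 0.00205).

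In cluster 4, Grap (chromosome 11, 61653265 to 61672784), an adaptor gene near Il4, was 16.1-fold higher (12.1 to 22), Chil3 4.85-fold (4.57 to 5.14; 3.14-fold in the uncorrected table) and Retnlg 3.45-fold (3.12 to 3.81; 2.01-fold without the highest Scrublet scores). Pttg1 was 3.98-fold lower (3.43 to 4.65), Atp11a 3.32-fold (2.71 to 4.08) and Nupr1, a stress response gene, 2.97-fold (2.57 to 3.43). Its granule genes (median log2 ratio 0.44), interferon genes (0.43) and anti-apoptotic genes (0.34) were higher as in neutrophils. In cluster 18, Cox6a2, a plasmacytoid dendritic cell marker, was 5.92-fold higher (4.79 to 7.38; 12-fold without the highest Scrublet scores), Tgtp2 4.44-fold (3.48 to 5.72) and Ly6a 3.43-fold (3.19 to 3.70). The Cox6a2 counts came from 7 WT and 25 IL-4 KO cells. The dendritic cell markers Ccr7, Siglech and Xcr1 were found in 30.3%, 22.5% and 23.6% of cluster 18. Its values therefore do not separate the mix of cell types from levels within cells. Interferon genes were higher in 19 of 21 cases (0.88), and cytokine genes lower in 10 of 11 (−1.19) beside 17 of 18 stress genes (−0.73). Retnla was at least 204-fold lower, from 1 WT cell, Scgb1a1 26.0-fold lower (21.8 to 31.3; ratio 1.08 without the top cell of each genotype) and Apoe 6.15-fold lower (5.75 to 6.57; ratio 0.802 without the highest Scrublet scores).

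**Figure D4:**
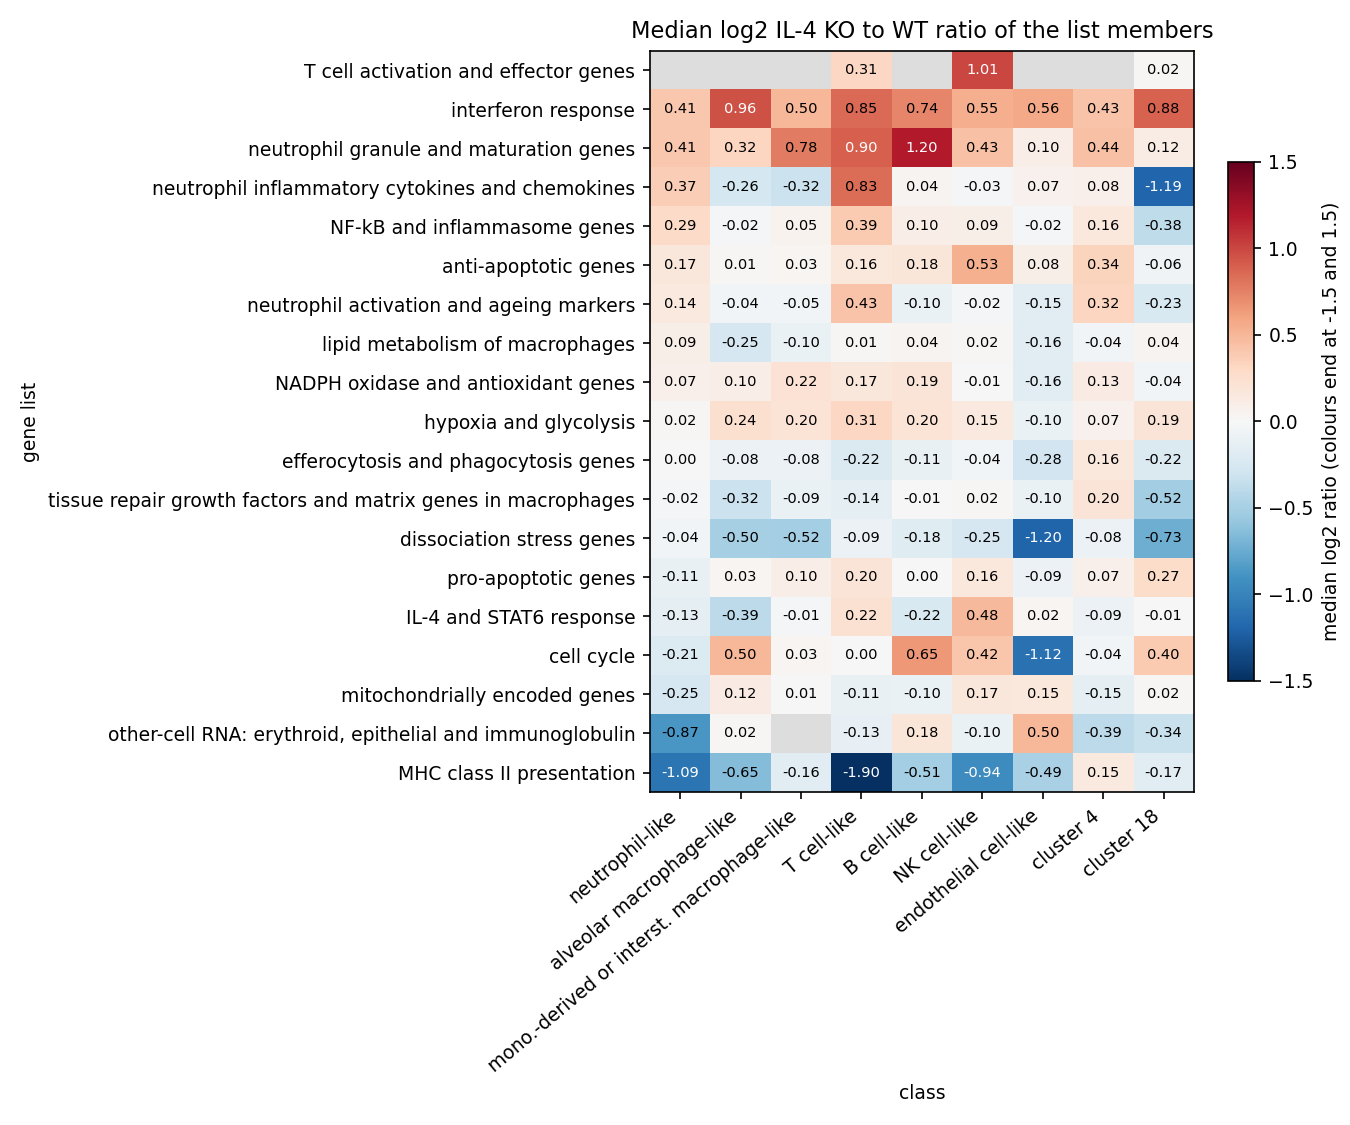
Median log2 IL-4 KO to WT ratio of the measured members of each gene list (vertical) in each class (horizontal), red for higher and blue for lower in IL-4 KO, grey where fewer than 5 members were measured. The interferon response list is above 0 in all 9 classes (0.41 to 0.96) and the dissociation stress list below 0 in all 9 (−1.20 to −0.04), but in NK cells they turned to −0.0979 and 0.19 at Leiden resolution 2, and the stress list of B cells to 0.00977 after thinning.

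Transcripts of the IL-4 receptor chains were present in the classes compared. Il4ra (chromosome 7, 125552120 to 125579474), the alpha chain, was at 112 CPM in WT neutrophils (103 to 121) and 122 CPM in IL-4 KO ones (117 to 127), and at 107 CPM in endothelial cells of both genotypes. It was lower in IL-4 KO B cells (82.6 CPM, 75.3 to 90.4, in WT and 59.8 CPM, 52.1 to 68.3, in IL-4 KO), T cells (86.3 CPM, 79.1 to 94.0, and 64.8 CPM, 57.3 to 73.1), alveolar macrophages (45.0 CPM, 42.7 to 47.4, and 39.0 CPM, 36.9 to 41.2) and cluster 4 (111 CPM, 103 to 121, and 83.7 CPM, 75.7 to 92.4). It was found in 28.4% of WT and 29.9% of IL-4 KO neutrophils, and in 16.6% (13.9 to 19.7%) and 15.9% (14.4 to 17.4%) after thinning to 2000 counts. Thinned shares were 9.70% and 10.5% of T cells, 12.1% and 10% of B cells and 7.95% and 8.32% of alveolar macrophages, so the lower CPM was not seen as a lower share in T cells and alveolar macrophages. NK cells had 5.56% (2.99 to 9.31%) and 7.19% (3.50 to 12.8%) after thinning. Il13ra1, which pairs with the alpha chain in the type II receptor, was found after thinning in 6.87% of WT neutrophils (5.05 to 9.09%; median 6774 counts) and 6.23% of IL-4 KO ones (5.29 to 7.29%; median 6907.5 counts). T cells, which largely lack it, had 0.462% (0.0560 to 1.66%; median 10767 counts) and 0.376% (0.00952 to 2.08%; median 11755 counts), and unthinned shares were 12.4% and 12.1% of neutrophils against 2.54% and 1.88% of T cells. Il2rg, the common gamma chain of the type I receptor, was at 459 CPM in WT T cells (442 to 476) and 453 CPM in IL-4 KO ones (433 to 474), and at 99.5 CPM (91.2 to 108) and 112 CPM (107 to 117) in neutrophils, and was lower in IL-4 KO B cells (388 CPM, 372 to 405, and 282 CPM, 265 to 300.1).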

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

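Of the tests below, those on free Il4 RNA, on exchanged labels, on interferon genes of macrophages without chromosome 11 members, on alveolar macrophages and endothelial cells, and on lymphocytes per endothelial cell were chosen only after the result was seen.

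Il4 counts outside T cells and cluster 18 were more frequent in IL-4 KO cells, the genotype that lacks the cytokine, in a split of cells made after the counts were seen. Free RNA shared by the cartridge would give similar levels in both genotypes, and the IL-4 KO to WT ratio was 13.1 (7.32 to 25.7) there. Over all cells, where that split plays no part, levels were 0.329 CPM (0.242 to 0.436) in WT and 1.16 CPM (1.01 to 1.32) in IL-4 KO. They lay closer together after thinning, at 1.28 CPM in WT and 2.07 CPM in IL-4 KO. The all-cell levels cannot decide on free RNA, because they mix it with Il4 made by the cells themselves. Only the ratio of 13.1 speaks against free RNA, and it rests on that split and on unthinned counts. Exchanged labels would put most counts labelled IL-4 KO in T cells and cluster 18 if an intact gene is read mainly there, and 5.02% (2.53 to 8.81%) lay there, while the 75% of WT counts (60.4 to 86.4%) is partly set by the split. A candidate explanation is transcription from the altered allele, and it stays open because the labels do not say which part of Il4 is deleted.

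Interferon response genes were higher in IL-4 KO cells of all 9 classes in the main values, but the NK cell median was −0.0979 at Leiden resolution 2 and −0.15 without the highest Scrublet scores. Chromosome 11 members near Il4 may carry allele differences of the targeted strain, but without them 6 of 7 named classes stayed above the central 95% of random lists. Only monocyte-derived or interstitial macrophages, at −0.0258 (random −0.14 to 0.17), did not. With cluster 1 counted among them the value was 1.11. That cluster is led by interferon-inducible genes and is mostly IL-4 KO, so adding it raises the median and decides nothing about linkage in this class. RNA of the more numerous neutrophils may add to other classes: over the 6 other named classes the interferon excess per S100a8 and S100a9 excess was a median of 2.90 times that of IL-4 KO neutrophils (lowest 2.03), and this source and a response of the cells themselves cannot be told apart because the value lies between the bounds of 2 and 5 set before the test. In alveolar macrophages and endothelial cells the same measure was 11.1 and 64.1. These 2 classes were picked as the highest values (2.03 to 3.37 in the rest), so passing the bound of 5 was settled beforehand. As a description, RNA of average neutrophils would account for little of the excess there. The endothelial value divides by a small S100a8 and S100a9 excess, 299 CPM beside 5292 CPM in WT, so its size is uncertain. RNA of other classes, among them cluster 1, was not tested. Genotype, a linked gene acting at a distance and a difference between the animals or the tagged cell preparations were not tested.

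The neutrophil share was higher in IL-4 KO, by a smaller fold with cluster 4 counted as neutrophils (22.2% of WT and 41.3% of IL-4 KO cells). The tests here do not count that cluster as neutrophils. Hashtag errors as the source would bring the share ratio towards 1 among clearly tagged cells. It rose from 2.79 to 3.50 (3.11 to 3.94) where the larger hashtag was at least 10 times the other. That speaks against such errors, though the ratio did not stay near 2.79, the outcome set before the test for no such effect. The shares were then 7.89% of WT and 27.6% of IL-4 KO cells, so they depended on this limit. Loss of WT neutrophils confined to cells near the count limit would bring the ratio towards 1 among larger cells. It was 2.96 (2.62 to 3.34) among cells of 7200 counts or more, which speaks against such a confined loss. This cannot decide on WT neutrophils with fewer counts throughout, because a higher limit would remove more of them too. A gain of neutrophils with all else in fixed proportion would leave lymphocytes per endothelial cell equal, and the IL-4 KO to WT ratio was 0.550 (0.460 to 0.657). This follows from class shares already seen, with counting error only. It speaks against lymphocytes and endothelial cells keeping their proportion in these 2 samples, and does not decide whether neutrophils were gained. Genotype, recovery during dissociation and a difference between the animals or the tagged cell preparations, 1 per genotype, remain open.

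The hashtag library held 2018 counts of hashtag A964, to which no genotype was given, a signal in data not used in the comparisons, with at most 13 counts in any of 1332 barcodes against a median of 892 counts of the genotype hashtags per cell. The uncorrected table held 124 cells without a column in the corrected table, also not used in the comparisons.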

How the results depend on the processing

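No test of a cause was chosen for this part after the results, but these alternatives were: leaving out the highest Scrublet scores, cluster 4 as neutrophils, cluster 1 as monocyte-derived or interstitial macrophages, neutrophils without cluster 16, leaving out the 1 cell with the most counts, and lists without members near Il4. No paired analysis was possible because each genotype was 1 tagged sample. A value counts as the same inside the 95% interval of the main value (for a list, that of the median over its members), as reversed where a gene whose interval excludes 1, or a list outside the central 95% of random lists, turned direction, and as moved otherwise. Among 2163 gene values, 1456 stayed the same, 690 moved and 17 reversed. Among 2052 list values, 1959 stayed, 59 moved and 34 reversed. These totals include a setting without Scrublet removal, with 178 gene and 164 list values. It equals the main setting because Scrublet marked 0 cells, so its values were the same by design. Settings differed: 52 of 177 gene values stayed the same after thinning and 68 of 178 as a mean over cells. Counterparts of clusters 4 and 18 were not sought at other resolutions or with the stricter filter, so they have no values there. TMM and median-of-ratios factors reversed nothing. Depth limits Il4, with 48 counts in WT and 219 in IL-4 KO, and Il13, with 57 and 1. The cause of the moves was not tested.

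At Leiden resolution 0.5, monocyte-derived or interstitial macrophages were 32.1% of WT and 29.1% of IL-4 KO cells, and in NK cells the Cxcl3 ratio was 0.701, the IL-4 and STAT6 list −0.14 and stress genes 0.11. At resolution 2, NK cells were 3.68% and 1.53%, WT T cells 7.07%, those macrophages 15.5% and 9.93% and IL-4 KO neutrophils 34.9986%, with the IL-4 and STAT6 list of B cells at 0.0501, interferon genes of NK cells at −0.0979, stress genes of NK cells at 0.19 and lipid genes of endothelial cells at 0.0357. With the stricter cell filter, WT B cells were 7.46%, those macrophages 18.8% and 15.7%, the Ms4a7 ratio in B cells 1.02, stress genes of NK cells 0.23 and oxidase genes of endothelial cells 0.0114, and in neutrophils H2-Ab1, H2-Aa and H2-Eb1 had ratios of 1.36, 1.17 and 1.11. In the uncorrected table RNA of other cells was −0.43 in endothelial cells and 0.0345 in neutrophils.

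After thinning, cell cycle genes of B cells were −0.15, stress genes 0.00977 in B and 0.0208 in NK cells, mitochondrial genes of T cells 0.0671 and RNA of other cells in cluster 18 0.12. The alveolar macrophage ratios of Mki67 and Ptgs2 were 0.752 and 1.16. Il4 was 1.28 CPM in WT and 2.07 CPM in IL-4 KO, and Il4ra 127 CPM in WT neutrophils. As a mean over cells, the IL-4 and STAT6 list of B cells was 0.0186 and their cell cycle genes −0.27, stress genes of NK cells 0.15, mitochondrial genes of T cells 0.0622, RNA of other cells in cluster 18 0.31 and the T cell Gzmb ratio 0.945. For that B cell list, members of at least 50 CPM gave 0.31 and the mean over the list 0.20. With no filter on low values RNA of other cells in endothelial cells was −0.60, and without members near Il4 the interferon genes of monocyte-derived or interstitial macrophages were −0.0258. Reassigning genotypes at 3 times gave a neutrophil Scgb1a1 ratio of 3.68, the same hashtag held in 95.9% and 98.6% of cells at 2 times, and in 66.9% and 73.4% at 10 times.

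Without the highest Scrublet scores, IL-4 KO B cells were 2.79%, alveolar macrophages 8.53% and 6.25%, endothelial cells 5.88% and 4.69% and IL-4 KO neutrophils 35.7%. In NK cells the IL-4 and STAT6 list was −0.24, interferon genes −0.15 and stress genes 0.16. In T cells the Wfdc21 ratio was 0.623, cytokine genes −0.0581, granule genes −0.17, activation and ageing markers −0.0446 and NF-kB genes −0.0883. In cluster 18 the Scgb1a1 ratio was 1.18, repair genes 0.10 and RNA of other cells 0.0652. In neutrophils H2-Ab1, H2-Aa and Crip1 had ratios of 1.77, 1.73 and 1.30, and MHC class II genes 0.19. With cluster 4 as neutrophils that class was 22.2% of WT and 41.3% of IL-4 KO cells. With cluster 1 as monocyte-derived or interstitial macrophages that class was 31.7% of WT and 31.6% of IL-4 KO cells, and its interferon genes were 1.14, or 1.11 without members near Il4. Without cluster 16 the neutrophil ratios of Ngp and Ifit3 were 1.03 and 1.28. Without the 1 cell with the most counts the Scgb1a1 ratio in cluster 18 was 1.08.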

Other observations

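The genes and cells in this part were chosen only after the results were seen, and so was the test against random sets of genes.

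Of 6085 genes measured in at least 5 of the 7 named classes, 10 lay past 1.62-fold in one direction in all classes where they were measured. Higher in IL-4 KO were Serpina3g (median 2.06-fold, 1.75 to 7.44), Wfdc21 (2.70-fold, 1.71 to 7.89), Gbp2 (3.08-fold) and Wdfy1 (3.63-fold, 1.68 to 4.48), beside Tgtp1, Tgtp2 and Cstdc4. Marco was higher too (6.33-fold, 3.03 to 29.9) in 5 measured classes, among them alveolar macrophages, which it helps to name. Without the highest Scrublet scores the Wfdc21 ratio in T cells was 0.623 and the Cstdc4 ratio in endothelial cells 1.32. Fbxo32 (median 2.75-fold, 1.83 to 3.37) and Rasgef1b (2.43-fold, 1.76 to 3.98) were lower.

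The 28 genes within 2 Mb of Il4 on chromosome 11 had a mean absolute log2 ratio of 0.19, inside the range of random sets (percentile 81.0). The 57 genes within 5 Mb had 0.31 and the 162 genes within 20 Mb had 0.23, both above all random sets (mean 0.16). Pttg1, within 20 Mb but not within 5 Mb, was lower in 6 of 7 named classes.

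Cells with at least 3 of 7 basophil markers were 14 in WT and 8 in IL-4 KO, and the WT ones held 20 Il4 counts in 6 cells against 1 count in IL-4 KO.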
